A study of Mus musculus with 6 samples.

How the data were processed

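RNA from bone marrow-derived macrophages of wild-type and IκBβ-knockout mice, unstimulated or after 1 h or 5 h in 1 µg/ml LPS, was measured on 6 Mouse Genome 430A 2.0 arrays, 1 for each genotype and time. The values are intensity, per the labels: MAS5 signals that the authors computed for 22690 probe sets on each array, on a linear scale. The MAS5 version, the scaling target and whether arrays of a genotype share an animal are not given in the sources used here. The mean of each array without its highest and lowest 2% was 500.2 to 500.3, so the arrays had been scaled to a common trimmed mean. Array medians were 113.5, 105.1 and 70.7 in wild type and 117.1, 98.7 and 65.2 in knockout at 0 h, 1 h and 5 h, and the highest signal on any array was 25581. The ratio of the 3' to the 5' control probe set was 0.994 to 1.12 for actin and 0.695 to 0.747 for Gapdh. The 9 probe sets of spiked-in controls had changed, against 0 h of the same genotype, by a mean log2 of −0.04 in wild type and 0.18 in knockout at 1 h, and by 0.18 and 0.19 at 5 h.

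Signals were used at the deposited scale. Those under 18.3, the 25th percentile of all values, were raised to it before log2 was taken, so a change from or to the floor is a bound. Of the probe sets, 20393 have 1 gene symbol, 691 have several, 64 are controls and 1555 have no gene given in the annotation used here. A probe set was kept if it exceeded its array's median on at least 1 array, and each gene was represented by its probe set with the highest mean, which left 7507 genes. The place of the Nfkbib probes relative to the deleted sequence is not given in the sources used here. Gene order and chromosomes were taken from a RefSeq gene table.

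The LPS changes at 1 h and 5 h and the genotype difference were estimated with limma 3.58.1 in R 4.3.3, with genotype and time as additive terms. This leaves 2 residual degrees of freedom, moderated with a prior of 2.19. It treats the LPS change as shared by the genotypes, and the spread it uses does not cover that between animals. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The difference between genotypes at a single time, and the LPS change within a genotype, rest on 2 arrays and are given as values, with counts at 2-fold. Their spread over genes (SD of knockout minus wild type) was 0.35, 0.39 and 0.48 at 0 h, 1 h and 5 h. Genes lower or higher at all 3 times were counted at 1.5-fold.

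Gene lists numbered 24: NF-kB subunits, inhibitors and IKK, cytokines, chemokines, immediate early and MAPK feedback genes, interferon-stimulated genes, late LPS effectors, negative feedback, Toll-like receptor signalling, macrophage identity, cholesterol biosynthesis, cell cycle, glycolysis and hypoxia, lysosome, oxidative phosphorylation, ribosomal proteins, housekeeping, sex-linked genes, and markers of MHC class II and dendritic cells, neutrophils, fibroblasts, B cells, T and NK cells, mast cells and erythroid cells. The 18 lists with at least 5 measured members were tested with limma's camera at an inter-gene correlation of 0.01 and again with the correlation estimated. The estimate rests on the 2 residual degrees of freedom. With it, camera's adjusted p also rose for lists whose estimate was negative, such as NF-kB (−0.063) at 1 h, from 9.22e-10 to 0.0636. A call lost in this way is thus no measure of the correlation within a list. For knockout minus wild type, a list median was set against 10000 random lists of the same size drawn within 20 bins of mean signal, with the 2.5th to 97.5th percentile as the range. Such a percentile describes genes on 2 arrays and is no test between animals. LPS-induced genes were those at least 4-fold up on the mean of the genotypes, split into early (at 5 h at least 2-fold below 1 h), sustained (4-fold at both times) and late (under 2-fold at 1 h); a gene can be in the early and the sustained class.

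The named genes follow a rule: Nfkbib; the 10 largest rises and 6 largest falls among genes called at each LPS time and changed at least 2-fold in both genotypes; the 8 largest differences each way between the genotypes at each time with both signals above the floor and the brighter above its array's median; the 6 each way with the largest smallest difference over the 3 times; 16 genes fixed in advance (Tnf, Il1b, Il6, Il10, Il12b, Cxcl1, Cxcl2, Ccl2, Ccl5, Nfkbia, Rel, Ptgs2, Nos2, Ifit1, Cxcl10 and Ifnb1); and the extreme members of each list. The groups, tests, lists, thresholds and this rule were set before the data were examined. Il1a between the genotypes, Dhx58 at 0 h, Cd22 and the 11 genes of chromosome 7, all named outside the rule, the chromosome count, the minimum signal of 200, and random lists matched on the signal at each time were chosen after the values were seen.

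The fit was tested on simulated data with 7507 genes, 100 of them changed by each fold. At 2-fold it recovered 77% at 1 h, 83% at 5 h and 87% for the genotype difference, and at 4-fold 96%, 98% and 97%, with 13, 20 and 17 false calls. The simulated noise was normal, independent between genes and drawn with the moderated SDs of the fit. No floor and no genotype-by-time difference were simulated, so recovery in the real data can be lower. Nfkbib, at −5.02 over the 3 times, had adjusted p = 0.305 in limma's test of the genotype difference. Simulated lists of 20 genes shifted by 0.3 fell outside the random range in 20 of 20 runs, and unshifted ones in 1 of 20. The alternatives tried were quantile normalization, median centring, floors at the 10th and 40th percentile, a pseudocount in place of the floor, no expression filter, a filter on all 6 arrays, the mean over a gene's probe sets, limma with a trend and robust prior, leaving out each array or each time, camera with the correlation estimated, genes with at least 200 on the brighter array, genes off the sex chromosomes and the chromosome of Nfkbib, and the other matching of random lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe sets with several genes or none were left out of all tests of genes.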

Results

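Nfkbib, the gene that encodes IκBβ, gave signals of 477 at 0 h, 3330 at 1 h and 5007 at 5 h of LPS on the wild-type arrays, and of 30.5, 136 and 56.1 on the knockout arrays. Knockout minus wild type was −3.97, −4.62 and −6.48 on the log2 scale, with every signal above the floor of 18.3. Xist, the RNA that coats the inactive X chromosome, read 52.1, 80.4 and 62.2 in wild type and 5634, 4189 and 2149 in knockout. The Y-chromosome genes Eif2s3y, Uty and Kdm5d were bright in wild type at 0 h (799, 289 and 279) and read 3.27, 0.77 and 20.6 in knockout at 0 h. The wild-type arrays thus carry male and the knockout arrays female RNA, so every difference between the genotypes below is also a difference between the sexes. Each genotype and time has 1 array, and values that compare single arrays come without a test.

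**Figure D1:**
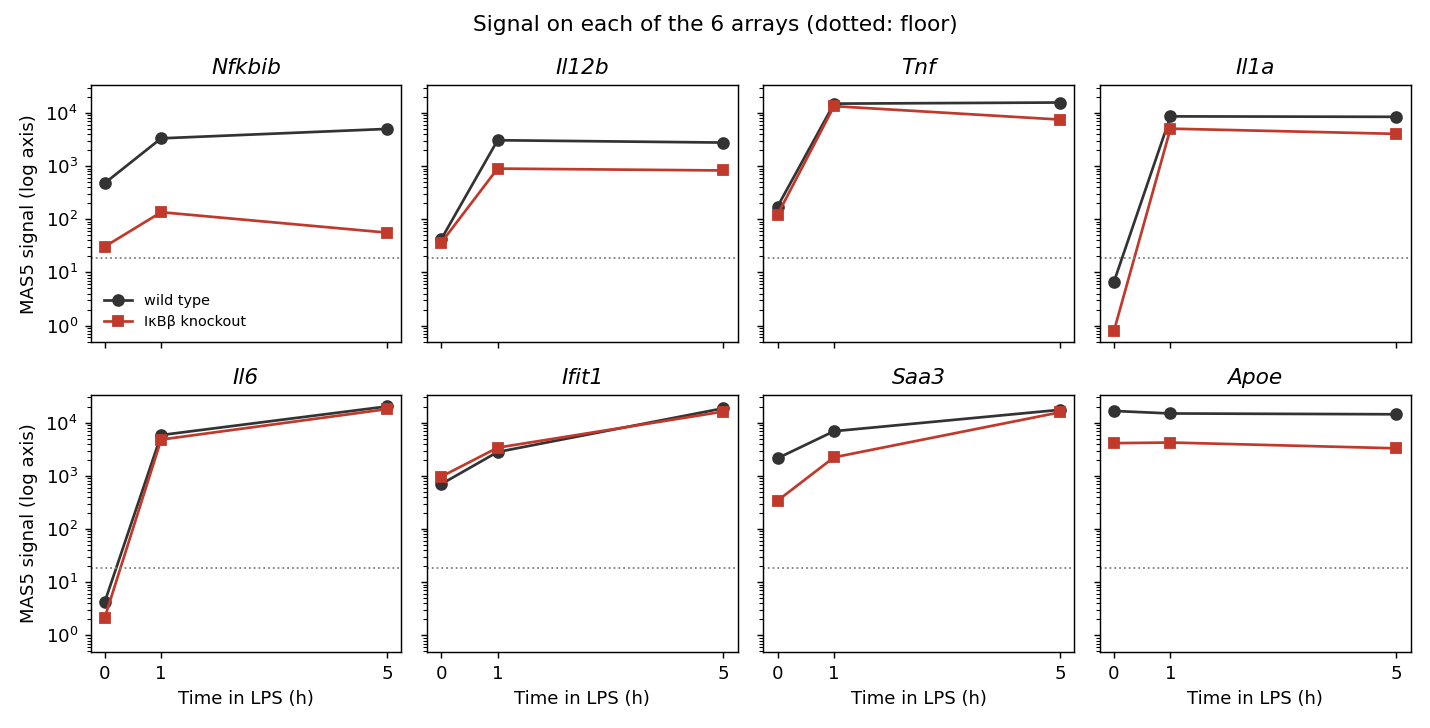
Signal of Nfkbib, Il12b, Tnf, Il1a, Il6, Ifit1, Saa3 and Apoe on each of the 6 arrays, on the deposited MAS5 scale. The dotted line is the floor to which lower signals were raised before folds were taken. Saa3 and Apoe lie on the chromosome of Nfkbib. Each point is a single array.

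At 1 h of LPS, Il1a, Ptgs2, Serpinb2 and Il6 rose by at least 8.50, 8.35, 8.20 and 8.18 on the log2 scale, as their signals at 0 h were under the floor. Socs3, an inhibitor of cytokine receptor signalling, rose by 8.17, and Il1b by 7.54, Cxcl1 by 6.70, Tnf by 6.61 and Tnfsf9 by 6.50. Dusp2 rose by at least 6.94, as its knockout signal at 0 h was under the floor. Ifnb1, the interferon beta gene, rose by 4.74 at 1 h (adjusted p = 0.00478) and stood at 0.61 at 5 h (adjusted p = 0.132). The largest falls were those of Zfp472 (−3.37), Frat2 (−3.37), Cnr2 (−3.25), Txnip (−3.21), Zfp688 (−3.20) and Hhex (−3.08), where Frat2 and Zfp688 ended under the floor. Limma's test of the change shared by both genotypes called 408 genes higher and 439 lower of 7507, of which 302 and 208 also changed at least 2-fold. The adjusted p was 0.00145 for Il1a (SE 0.29), 0.00161 for Tnf (SE 0.24) and 0.0126 for Zfp472 (SE 0.34). The median of all genes was −0.18, and 48.2% of the calls were higher, against 56.4% after quantile normalization and 66.8% after median centring. Without the wild-type 1 h array the counts were 100 higher and 12 lower, without the knockout 1 h array 101 and 16, without the wild-type 0 h array 195 and 58, and without the knockout 0 h array 200 and 51.

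Cytokines had a median log2 change of 4.27 at 1 h: 18 of 22 rose, none fell and 4 did not pass, and adjusted over the list alone 19 rose. Il10 rose by 5.41 and Il12b by 5.42, while Tgfb1 (−0.17) and Il18 (0.00) did not pass. Among 20 chemokines (median 3.49) 12 rose, 0 fell and 8 did not pass, and adjusted over the list alone 16 rose; Ccl7 rose by 6.35, Ccl2 by 6.21, Cxcl2 by 4.33, Cxcl10 by 4.31 and Ccl5 by 3.54. Of 28 immediate early and MAPK feedback genes (median 2.75) 22 rose, 0 fell and 6 did not pass, 25 rose adjusted over the list alone, and Fos (0.20) and Jun (0.42) were lowest. Negative feedback genes (22, median 2.45) gave 17 risen, 0 fallen and 5 not passed, with Tnfaip3 at 5.69 next to Socs3, and 20 risen adjusted over the list alone. Late LPS effectors (35, median 2.04) gave 23, 0 and 12, with Acod1 at 4.66, and 24 risen adjusted over the list alone. The camera set test gave adjusted p = 3.2e-24 for cytokines, 2.29e-19 for chemokines, 1.7e-30 for immediate early genes, 3.2e-24 for negative feedback and 1.74e-25 for late effectors, and adjusted p = 0.0462 for each of these 5 with an estimated correlation.

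The 16 genes for NF-kB subunits, inhibitors and IKK had a median of 1.13 at 1 h: 10 rose, 1 fell and 5 did not pass, and adjusted over the list alone 10 rose and 2 fell. Rel, an NF-kB subunit, rose by 4.69 (adjusted p = 0.00161), and Nfkbia, the IκBα gene, by 0.83 (adjusted p = 0.0455) on its brightest probe set and by 1.66 as the mean of its 4 probe sets. Nkiras2 fell by 0.78, but after median centring 0 genes of this list were called lower. Toll-like receptor signalling genes (25, median 0.22) gave 7 risen, 1 fallen and 17 not passed, with Tlr2 at 1.94 and Tab1 at −1.32, and 8 risen and 3 fallen adjusted over the list alone. Camera gave adjusted p = 9.22e-10 for the NF-kB list (adjusted p = 0.0636 with an estimated correlation) and 0.000124 for Toll-like receptor signalling (adjusted p = 0.122 with an estimated correlation).

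Interferon-stimulated genes were little changed at 1 h, with a median of 0.06 over 40 genes: 8 rose, 1 fell and 31 did not pass, and 10 and 3 adjusted over the list alone. Mx2 (at least 2.93), Oasl1 (2.79) and Ifit1 (1.91) rose, and Stat2 fell by 0.74. After median centring 0 genes of this list were called lower. Glycolysis and hypoxia genes (21, median 0.02) gave 6 risen, 0 fallen and 15 not passed, with Adm at 2.80 and the glucose transporter Slc2a1 at 2.15, and 8 risen adjusted over the list alone. The MHC class II and dendritic cell list (11, median 0.01) gave 1 risen (Cd83, 2.65), 0 fallen and 10 not passed, and its median was −0.01 after quantile normalization. Interferon-stimulated genes had a camera adjusted p = 0.00017 (adjusted p = 0.584 with an estimated correlation), glycolysis genes 0.00122 (adjusted p = 0.338 with an estimated correlation) and the MHC class II list 0.0423 (adjusted p = 0.667 with an estimated correlation). Oxidative phosphorylation genes (31, median −0.21, with 0 risen, 0 fallen and 31 not passed) were the list below the others by camera, at adjusted p = 0.0181 (adjusted p = 0.223 with an estimated correlation).

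Lists with little change at 1 h were macrophage identity (31 genes; 1 rose, Cebpb by 1.10, and 1 fell, Irf8, with 29 not passed), cholesterol biosynthesis (18; 1 rose, 2 fell and 15 did not pass; 4 and 4 adjusted over the list alone) and cell cycle (27; 1 rose, Mki67 by 2.41, 2 fell and 24 did not pass). None of 25 lysosomal, 24 ribosomal protein, 15 housekeeping and 5 neutrophil genes passed the test. The medians of these 7 lists were −0.10, −0.12, −0.10, −0.17, −0.13, −0.11 and −0.03 in that order, near the −0.18 of all genes, and each of these 7 medians was above 0 after median centring, as was that of cell cycle genes after quantile normalization. Camera gave adjusted p = 0.96, 0.594, 0.682, 0.502, 0.465, 0.815 and 0.714 in that order (adjusted p = 0.978 for macrophage identity and 0.83 for the other 6 with an estimated correlation).

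At 5 h of LPS, Il6 and Ptgs2 rose by at least 10.03 and 9.77 on the log2 scale, and Serpinb2 by 8.70, Il1a by 8.32, Upp1 by 8.29, Edn1 by 8.15 and Nos2 by 8.15, all bounds because the 0 h signals were under the floor. Lcn2, which encodes an iron-siderophore-binding protein, rose by 8.59, Socs3 by 8.18 and Cxcl9 by 8.07. Nos2, the inducible nitric oxide synthase gene, was under the floor at 0 h and 1 h in both genotypes and read 4596 in wild type and 5881 in knockout at 5 h. The largest falls were those of Sesn1 (−7.11), the chemokine receptor gene Cxcr4 (−6.16), Nfic (−5.96), the iron exporter gene Slc40a1 (−5.84), Dbp (−5.73) and Pdxk (−5.70), with Nfic and Dbp ending under the floor. Limma called 1463 genes higher and 4045 lower, of which 893 and 2593 changed at least 2-fold, with adjusted p = 0.000329 for Il6 (SE 0.12) and Sesn1 (SE 0.19). The median of all genes was −0.56, and 26.6% of the calls were higher, against 39.3% after quantile normalization (median −0.22) and 59.1% after median centring (median 0.20). The number of small falls at 5 h thus follows the scaling, and the changes of the lists below are set against the −0.56 of all genes.

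Interferon-stimulated genes rose late: at 5 h 38 of 40 rose, 0 fell and 2 did not pass, with a median of 3.10, which is 3.67 above the median of all genes. Mx2 rose by at least 6.65, as its wild-type signal at 0 h was under the floor, Iigp1 by 5.75 and Ifit1 by 4.41. Irf9 (0.25) and Ifitm3 (0.27) did not pass. Late effectors (median 3.48) gave 34 risen, 0 fallen and 1 not passed (Clec4d), cytokines (4.72) 17, 1 and 4, chemokines (4.43) 16, 1 and 3, and negative feedback genes (2.58) 18, 1 and 3. Adjusted over the list alone, chemokines gave 18 risen and 1 fallen. The 1 chemokine gene that fell, Ccl6 (−0.59), stood at 0.17 after median centring, and Tgfb1 (−0.88) and Il1r2 (−0.92) fell among the others. After median centring 0 cytokine, chemokine and negative feedback genes were called lower, and after quantile normalization 0 negative feedback genes. Cxcl11 rose by 7.15 and Il10 by 6.66, and Cxcl10 (5.14), Ccl5 (4.40), Ccl2 (6.15), Cxcl2 (4.18), Tnf (6.22), Il1b (7.46) and Il12b (5.29) stayed high, while Cxcl1 had come down from 6.70 at 1 h to 4.58. Camera gave adjusted p = 5.1e-24 for interferon-stimulated genes (adjusted p = 0.171 with an estimated correlation). It gave 2.09e-22 for late effectors, 6.64e-12 for cytokines and chemokines and 1.5e-11 for negative feedback (adjusted p = 0.0976 for these 4 with an estimated correlation).

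Immediate early genes had come down to a median of 1.10 at 5 h, with 18 risen, 3 fallen and 7 not passed. Egr2 (−1.69) and Klf2 (−1.23) fell, while Ptgs2 and Dusp2 (at least 7.63) stayed high. Only 1 gene of this list was called lower after quantile normalization, and 1 after median centring. The NF-kB list (median 1.13) gave 13 risen, 1 fallen and 2 not passed: Tnfaip3 rose by 5.74, Nfkbiz by 3.90, Rel by 3.76 and Nfkbia by 0.91 (1.67 as the mean of its probe sets). Ikbkg fell by 0.79 on its brightest probe set and stood at 0.35 as the mean of its probe sets. Glycolysis and hypoxia genes (median 0.98) gave 14 risen, 2 fallen and 5 not passed: Pfkfb3 rose by 5.27 and Slc2a1 by 3.14, Vegfa fell by 2.27, and Aldoa fell by 0.46 but stood at 0.30 after median centring. Toll-like receptor signalling genes (median 0.40) gave 12 risen, 6 fallen and 7 not passed, with Tlr3 at 3.10 and Mapk14 at −3.03. Immediate early genes had a camera adjusted p = 9.5e-09 (adjusted p = 0.144 with an estimated correlation) and the NF-kB list 7.7e-08 (adjusted p = 0.0976 with an estimated correlation). Camera gave 4.93e-07 for glycolysis (adjusted p = 0.171 with an estimated correlation) and 0.001 for Toll-like receptor signalling (adjusted p = 0.163 with an estimated correlation).

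Cell cycle genes fell most among the lists at 5 h: 20 of 27 fell, 1 rose and 6 did not pass, with a median of −1.96 (−1.19 after median centring and −1.34 after quantile normalization). Cenpa fell by 4.08 and Mcm7 by 3.64, and Tpx2 rose by 2.57. Macrophage identity genes (median −0.24) gave 5 risen, 12 fallen and 14 not passed: the scavenger receptor gene Msr1 rose by 2.16 and Fcgr1 by 1.85, and the transcription factor gene Cebpa fell by 5.07 and Cx3cr1 by 2.16. Ribosomal protein genes (median −0.52) gave 0 risen, 20 fallen and 4 not passed, oxidative phosphorylation genes (−0.46) 1, 22 and 8, lysosomal genes (−0.64) 3, 16 and 6, cholesterol biosynthesis genes (−0.48) 6, 8 and 4, and housekeeping genes (−0.19) 2, 5 and 8. After median centring the medians of macrophage identity (0.52), ribosomal (0.25), oxidative phosphorylation (0.31), lysosomal (0.12), cholesterol (0.28) and housekeeping genes (0.57) were above 0, as was that of cholesterol genes after quantile normalization (0.07). The counts turned too: after median centring 21 macrophage identity genes rose and 5 fell, and the counts were 8 and 0 for ribosomal, 10 and 2 for oxidative phosphorylation, 8 and 7 for lysosomal, 8 and 4 for cholesterol and 10 and 1 for housekeeping genes. Adjusted over the list alone, 23 oxidative phosphorylation genes, 9 cholesterol genes and 4 housekeeping genes fell. Polr2a fell by 2.04, and Hprt fell by 0.68 but stood at 0.09 after median centring. Cell cycle genes had a camera adjusted p = 0.0208 (adjusted p = 0.315 with an estimated correlation) and ribosomal genes 0.0466 (adjusted p = 0.595 with an estimated correlation). Camera gave 0.828, 0.0833, 0.191, 0.391 and 0.557 for macrophage identity, oxidative phosphorylation, lysosomal, cholesterol and housekeeping genes (adjusted p = 0.905, 0.289, 0.717, 0.717 and 0.717 with an estimated correlation).

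Marker genes of other cell types were tested if a probe set with 1 gene symbol was above the array median on any array. Among genes with such a probe set, these were 11 of 16 MHC class II and dendritic cell, 5 of 15 neutrophil and 4 of 17 fibroblast genes. They were also 4 of 12 B cell, 1 of 15 T and NK cell, 2 of 10 mast cell and 1 of 8 erythroid genes. The lists hold 19, 18, 18, 13, 16, 11 and 11 genes in that order. At 5 h the MHC class II and dendritic cell list (median −0.24, but 0.53 after median centring) gave 4 risen, 3 fallen and 4 not passed, with Ccr7 at 2.14 and H2-DMa at −1.56. Neutrophil genes gave 2 risen, 1 fallen and 2 not passed, with S100a8 at 3.15 and Mmp8 at −1.47. Camera gave adjusted p = 0.361 and 0.191 for these lists (adjusted p = 0.717 and 0.595 with an estimated correlation). Among the fibroblast genes Dcn rose by 1.68 (adjusted p = 0.0424; 0 adjusted over the list alone), and Vim, Fn1 and Acta2 did not pass. Ighm, the IgM heavy chain gene, read 3371 in wild type and 3571 in knockout at 0 h and fell by 3.60 at 5 h, and Cd79b fell by 2.06 and Cd22 by 1.18. Gzmb rose by 1.62 and Hdc, the histidine decarboxylase gene, by at least 5.32 at 5 h, while Gata2 (0.45) and Epor (0.09) did not pass.

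Apoc2 and Apoe, which encode apolipoproteins, stood −2.12 (SE 0.10) and −1.98 (SE 0.10) in knockout against wild type over the 3 times, and Xist 5.86 (SE 0.34), each the same way in 3 of 3 pairs of arrays. Eif2s3y, on the Y chromosome, was the only gene that passed limma's test of a genotype difference shared by the 3 times (adjusted p = 0.0177, lower in 3 of 3 pairs). Its log2 difference of −5.32 is a bound, as its 3 knockout signals were under the floor. The next adjusted p values were 0.073 for Apoc2, 0.0734 for Apoe and 0.0914 for Xist. The test called 0 genes higher and 1 lower, and 631 genes had an unadjusted p under 0.05. The call of Eif2s3y depended on the floor, the filter and the arrays used: with the floor at the 10th percentile, or without the expression filter, 0 genes were called lower. Nor was any gene called lower without the wild-type or the knockout array of 1 h or of 5 h, and 1 gene was called higher without the wild-type or the knockout array of 0 h. The 4 measured sex-linked genes all passed adjusted over the list alone. Among lists, interferon-stimulated genes were higher in knockout by camera (adjusted p = 5.2e-07; adjusted p = 0.563 with an estimated correlation). Negative feedback genes were higher too (adjusted p = 0.0381; adjusted p = 0.563 with an estimated correlation), and ribosomal (adjusted p = 0.00058), cell cycle (adjusted p = 0.000998) and oxidative phosphorylation genes (adjusted p = 0.0302) were lower (adjusted p = 0.563 for these 3 with an estimated correlation).

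Before LPS, the acute-phase gene Saa3 read 2145 in wild type and 343 in knockout (−2.65), and Apoe, a lipid carrier of macrophages, 16644 and 4125 (−2.01). Apoc2 stood at −2.26, Art1 at −2.52, Arhgap35 at −2.66, Dpf3 at −2.73 and Kdm5d at −3.76. Saa3, Apoe, Apoc2, Art1, Arhgap35 and, among the higher genes, Rasgrp4 lie on the chromosome of Nfkbib, which was looked up after the values were seen. Highest after Xist (6.76), among genes above the floor on both arrays, were Rasgrp4 (2.69), Slc30a3 (2.52), Erdr1 (1.98), Irf4 (1.79), Gdf3 (1.77), Slc16a11 (1.59) and Sncb (1.49). Erdr1 read 551 and 2173, while Rasgrp4, Slc30a3, Irf4, Slc16a11 and Sncb read 145 or less on both arrays. In all, 67 genes were at least 2-fold higher and 85 lower in knockout at 0 h. With at least 200 on the brighter array, a minimum chosen after the data were seen, 5 and 14 were left.

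At 1 h of LPS, Il12b, which encodes the p40 subunit of interleukins 12 and 23, read 3067 in wild type and 899 in knockout (−1.77), and its second probe set 2715 and 681. Il23a, the other subunit of interleukin 23, stood at −1.96, Il1a at −0.77 and Tnf at −0.16, while the interleukin 1 receptor antagonist gene Il1rn stood at 0.95. Saa3 stood at −1.63, and Irf1, a transcription factor of the interferon response, at −1.05. Among genes above the floor on both arrays, those lowest after Nfkbib were Pkmyt1 (−2.57), Htra1 (−2.24), Nkain1 (−2.16), Krtap19-1 (−2.16), Apoc2 (−2.12) and Spint2 (−2.02), and those highest were Xist (5.70), Slc15a2 (2.77), Slc30a3 (2.67), Tmem267 (2.11), Mxd1 (1.92), Abhd1 (1.78), Erdr1 (1.73) and Gdf3 (1.71). Like Saa3, Htra1, Apoc2 and Spint2 lie on the chromosome of Nfkbib. On a second probe set Nkain1 read 46.1 in wild type and 50.7 in knockout. At 1 h 80 genes were at least 2-fold higher and 140 lower, and 19 and 34 with at least 200 on the brighter array.

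At 5 h, Il12b read 2771 in wild type and 828 in knockout (−1.74; −2.23 on its second probe set), Tnf 15715 and 7507 (−1.07) and Il1a 8452 and 4043 (−1.06). Cxcl1 stood at −0.73 and Cxcl2 at −0.44, whereas Il6 (−0.17), Ccl2 (−0.14) and Il10 (0.23) differed less, and Nos2 stood at 0.36. The interferon-inducible genes Ifi204 and Cxcl11 stood at 1.65 and 1.54. Among genes above the floor on both arrays, those lowest after Nfkbib were Apoc1 (−2.93), Hps1 (−2.78), Zap70 (−2.51), Nkain1 (−2.45), Rgs9 (−2.45), the chemokine gene Ccl24 (−2.30) and Pard3b (−2.25), and those highest were Xist (5.11), Igha (2.41), Ypel1 (2.26), Bmpr1a (2.19), Rgs16 (2.09), Sesn2 (2.06), Tmem216 (1.85) and Tm7sf2 (1.84), with signals of 114 or less apart from Xist. Other probe sets were mixed: that of Tmem216 read 44.8 in wild type and 7.4 in knockout. Those of Igha read 30 and 11.2, and 2.9 and 20.3. Those of Nkain1 read 59.1 and 54.9, and 49.9 and 21, while those of Rgs16 and Sesn2 were higher in knockout. At 5 h 134 genes were at least 2-fold higher and 228 lower, and 34 and 43 with at least 200 on the brighter array. For 2060 genes with 2 probe sets above the median on all arrays, 103 of the 118 that differed at least 1.5-fold at 5 h went the same way on the second probe set, against 54 of 62 at 1 h and 23 of 26 at 0 h. Size agreed less: of 15 genes that differed at least 2-fold at 5 h, 6 differed at least 1.5-fold the same way on the second probe set. At 1 h these were 4 of 6, and at 0 h 0 of 1. The correlation of the 2 probe sets was 0.272, 0.376 and 0.521 at 0 h, 1 h and 5 h across genes, which are not independent replicates.

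Interferon-stimulated genes were higher in the knockout before LPS: 37 of 40 members, with a median log2 difference of 0.32, above all 10000 random lists matched on signal (percentile 100). Random lists treat genes as independent, while the estimated correlation within this list is 0.309. Camera over the 3 times gave adjusted p = 5.2e-07, and adjusted p = 0.563 with an estimated correlation. That rise cannot be put down to correlation alone. Oxidative phosphorylation genes, with an estimate of −0.0319, went from adjusted p = 0.0302 to adjusted p = 0.563 in the same test. Mx2 stood at 1.67 or more, as its wild-type signal was under the floor, Ifit3 at 0.71, Dhx58 at 0.61 and Ifit1 at 0.47, and Ifitm3 (−0.12) was lowest. At 1 h the median was 0.21 (percentile 100; 33 members higher) with Oasl1 at 0.64 and Irf1 at −1.05. At 5 h, when LPS had induced the list in both genotypes, it was 0.04 (percentile 94.1; 22 members higher). Negative feedback genes had medians of 0.17 (percentile 99.99), 0.10 (percentile 98.7) and 0.01 (percentile 85.2) at 0 h, 1 h and 5 h, and camera gave adjusted p = 0.0381 (adjusted p = 0.563 with an estimated correlation). Socs1 stood at 1.16 at 1 h, and the Socs3 difference of 1.94 at 0 h rests on 1 of 3 probe sets, as the mean over its probe sets is −0.49.

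The median of cytokines was lower in the knockout at 1 h (−0.20, percentile 0.16; 14 of 22 members lower), and it was −0.15 at 5 h (percentile 5.84, and 2.18 against random lists matched on the signal at that time, a choice made after the data were seen). At 0 h the median was −0.01 (percentile 41.5). Il23a and Il12b were lowest at 1 h and Il12b and Tnf at 5 h. Members went both ways at 1 h, with 5 at least 1.5-fold higher (Il1rn, Tnfsf10, Csf3, Hbegf and Inhba) and 4 lower. Camera over the 3 times gave adjusted p = 0.183 for cytokines (adjusted p = 0.563 with an estimated correlation). Late LPS effectors had medians of −0.02 (percentile 46.5), −0.16 (percentile 0.06) and −0.12 (percentile 9.23), with Saa3 and the complement factor B gene Cfb (−1.34) lowest at 1 h, and camera gave adjusted p = 0.194 (adjusted p = 0.563 with an estimated correlation). Chemokines stayed within the random range at each time (medians −0.02, −0.01 and −0.03), with Ccl22 at 1.52 at 0 h and 1.24 at 1 h, and Cxcl11 and Ccl24 at the ends at 5 h. The NF-kB list also stayed within it (−0.07, 0.02 and −0.03). At 0 h Bcl3 stood at 0.53, Nkiras1 at −0.59 and Tnfaip3 at −0.59. At 5 h Nkap stood at 0.64, Relb at −0.41 and Nfkbia at −0.37. Immediate early genes had medians of −0.02, 0.09 (percentile 98.4 at 1 h) and −0.08, with Egr2 at −1.08 at 1 h and Egr3 and Nr4a1 at −2.34 and −1.23 at 5 h, and camera gave adjusted p = 0.408 (adjusted p = 0.71 with an estimated correlation).

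Cell cycle genes were lower in knockout at 0 h (22 of 27 members; median −0.23, percentile 0.09) and at 1 h (24 members; −0.29, percentile 0.32), and within the random range at 5 h (−0.11, percentile 35). Birc5 stood at −0.76 at 0 h, and Mki67 and Mcm2 at −1.16 and −1.10 at 1 h. Ribosomal protein genes stood at −0.15 at 0 h (23 of 24 lower; percentile 0.14), −0.07 at 1 h (percentile 2.86) and −0.14 at 5 h (percentile 12.4). Oxidative phosphorylation genes stood at −0.10 at 1 h (percentile 0.19) and within the range at 0 h (−0.07) and 5 h (−0.09). Glycolysis and hypoxia genes stood at 0.13 at 1 h and 0.13 at 5 h (percentile 99.7 at each) and at −0.04 at 0 h, with Pfkfb3 at 0.88 at 1 h and Vegfa at 1.11 at 5 h. Cholesterol biosynthesis genes were lower at 5 h (16 of 18; median −0.29, percentile 1.49), with Mvk at 73 in wild type and under the floor in knockout, and Cyp51 at −0.57, and stood at −0.09 and 0.03 at 0 h and 1 h. Tm7sf2, a member of this list, was higher at 5 h (1.84), at 19.7 in wild type and 70.5 in knockout. Glycolysis and cholesterol genes did not pass camera over the 3 times (adjusted p = 0.0699 and 0.112). Cell cycle, ribosomal and oxidative phosphorylation genes passed it (adjusted p = 0.000998, 0.00058 and 0.0302). With an estimated correlation none of these 5 lists passed camera (adjusted p = 0.61 for cholesterol and 0.563 for the others).

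Toll-like receptor signalling genes (0.07, percentile 98.1) and macrophage identity genes (−0.12, percentile 2.41) lay just outside the random range at 0 h, and inside it when the random lists were matched on the signal at 0 h (percentiles 96 and 3.26). Lbp stood at 1.09 and Traf6 at 0.57 at 0 h, and Cd36 at −0.55 next to Apoe. At 1 h and 5 h these lists were within the range (0.05 and 0.04; −0.02 and −0.10). Lysosomal genes (−0.05, 0.00 and −0.13), housekeeping genes (−0.04, 0.01 and −0.08), MHC class II and dendritic cell genes (0.09, 0.09 and −0.02) and neutrophil genes (0.02, −0.14 and 0.17) were within it at all 3 times. Ctsk stood at 0.59 at 0 h, Actb at −0.45 at 5 h, Ccr7 at 2.34 or more at 0 h and S100a8 at 1.18 at 5 h. In lists with fewer than 5 measured members, Dcn stood at −1.25 at 1 h, Vpreb3 at −1.87 at 0 h, Gzmb at 1.03 at 1 h, Gata2 at 1.22 at 0 h and Epor at −0.53 at 1 h.

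**Figure D2:**
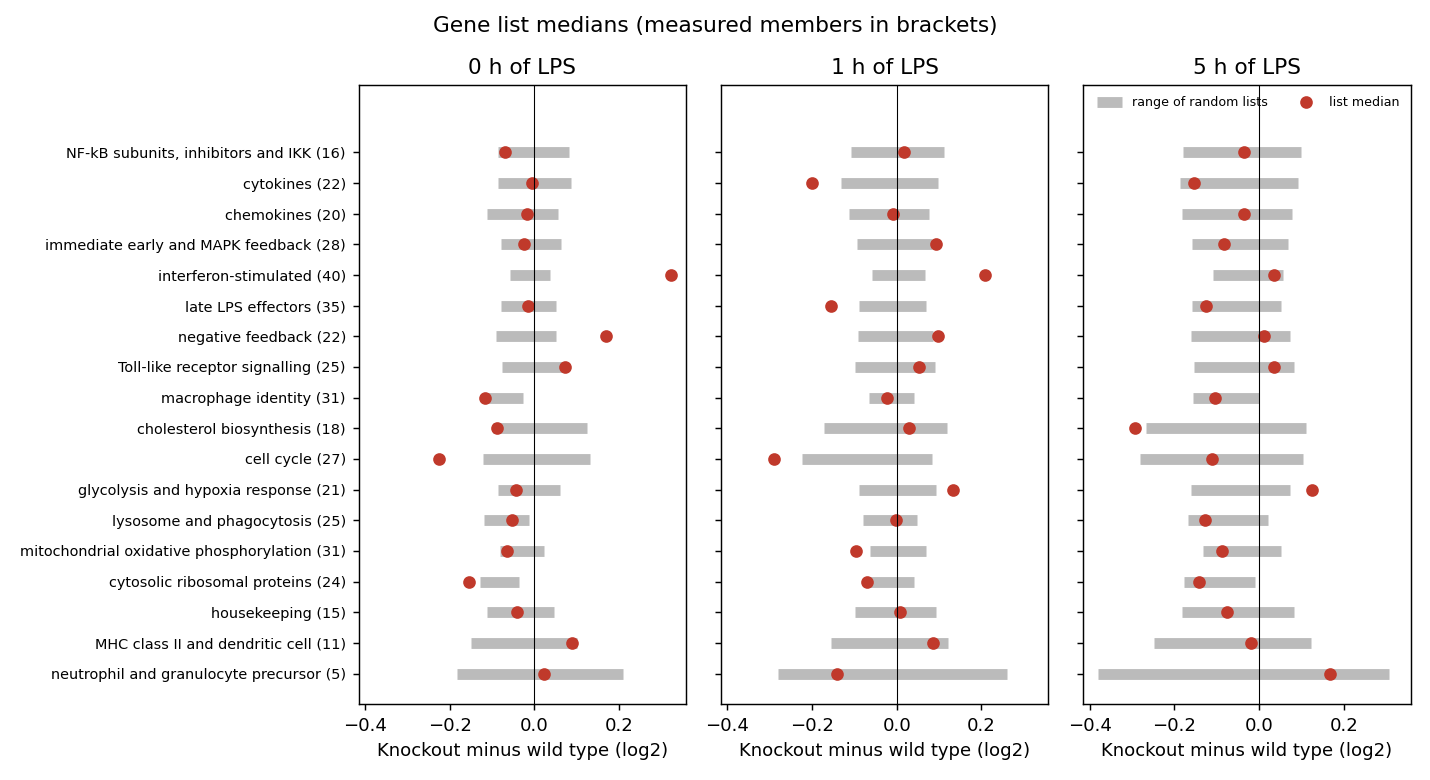
Median of knockout minus wild type for each gene list at 0 h, 1 h and 5 h of LPS, with the range of 10000 random lists matched on signal. Each value compares 2 single arrays, and the genotypes also differ in sex.

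The median of late-induced genes was higher in the knockout and that of early-induced genes lower at 5 h. The late class holds 240 genes, such as Nos2 and Cxcl9, that were at least 4-fold up at 5 h and under 2-fold at 1 h. Its medians were 0.05 at 0 h (percentile 99.99), 0.03 at 1 h (percentile 99.4) and 0.11 at 5 h (percentile 100), and without the interferon-stimulated list its median at 0 h was 0.02, within the random range (percentile 84.3). Its members went both ways: 24 were at least 1.5-fold higher and 12 lower at 0 h, 14 and 23 at 1 h, and 20 and 8 at 5 h. The early class, with 51 genes such as Ifnb1 and Cxcl1, stood at −0.03 at 0 h, −0.01 at 1 h and −0.23 at 5 h (percentile 0.1), with 31 members lower at 5 h. The 166 genes induced at 1 h stood at 0.00, −0.04 (percentile 4.08, and 1.61 against random lists matched on the signal at that time) and −0.10 (percentile 0.98), and the 415 induced at 5 h at 0.02, 0.03 (percentile 99.9) and 0.03 (percentile 100). Of these 415 genes, 30 were at least 1.5-fold higher and 41 lower at 1 h. The 112 sustained genes, Il6, Tnf and Il1b among them, stood at 0.00 at 0 h, −0.05 at 1 h (percentile 1.89; 0.05 after median centring) and −0.08 at 5 h (percentile 9.27). The LPS changes within each genotype were alike in number: 417 genes were at least 2-fold higher and 308 lower at 1 h in wild type against 393 and 370 in knockout, and 951 and 2518 at 5 h against 955 and 2756. The correlation of knockout with wild type at the same time was 0.984, 0.983 and 0.984 across genes, which are not independent replicates, and that of 0 h with 5 h was 0.884 in wild type and 0.880 in knockout.

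Apoe, Apoc2 and Apoc1, which are neighbours on chromosome 7, the chromosome of Nfkbib, were at least 1.5-fold lower in the knockout at all 3 times. With every signal above the floor, 12 genes were lower and 10 higher in this way. The lower ones with the largest smallest difference were Nfkbib (−3.97), Apoc2 (−1.97), Apoe (−1.82), Adat2 (−1.01), Art1 (−0.95) and Dnajb13 (−0.91). The higher ones were Xist (5.11), Erdr1 (1.23), Gdf3 (1.22), Cdk5rap1 (0.95), F5 (0.95) and Arhgef18 (0.79). With signals raised to the floor included, 24 were lower and 18 higher. Apart from Nfkbib, 11 of the 20 lower genes on autosomes lie on chromosome 7, which holds 554 of the 7283 tested autosomal genes (7.61%), against 0 of 16 higher genes. The 11 are Hif3a, Qpctl, Mark4, Apoc2, Apoc1, Apoe, Mrps12, Fah, Dnajb13, Art1 and Htra1, and this count was made after the values were seen. Mrps12 read 713 in wild type and 396 in knockout at 0 h, Mark4 reached 318, and Hif3a, Qpctl, Fah, Dnajb13, Art1 and Htra1 read 176 or less on every array. Other probe sets were mixed. Those of Mark4 were lower in knockout at all 3 times, and that of Htra1 at 5 h (65.3 and 14.6). That of Qpctl stood at −0.98, −0.40 and 1.41. A dim one of Art1 read 6, 10.1 and 18.7 in wild type and 28.2, 25.2 and 53.4 in knockout.

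**Figure D3:**
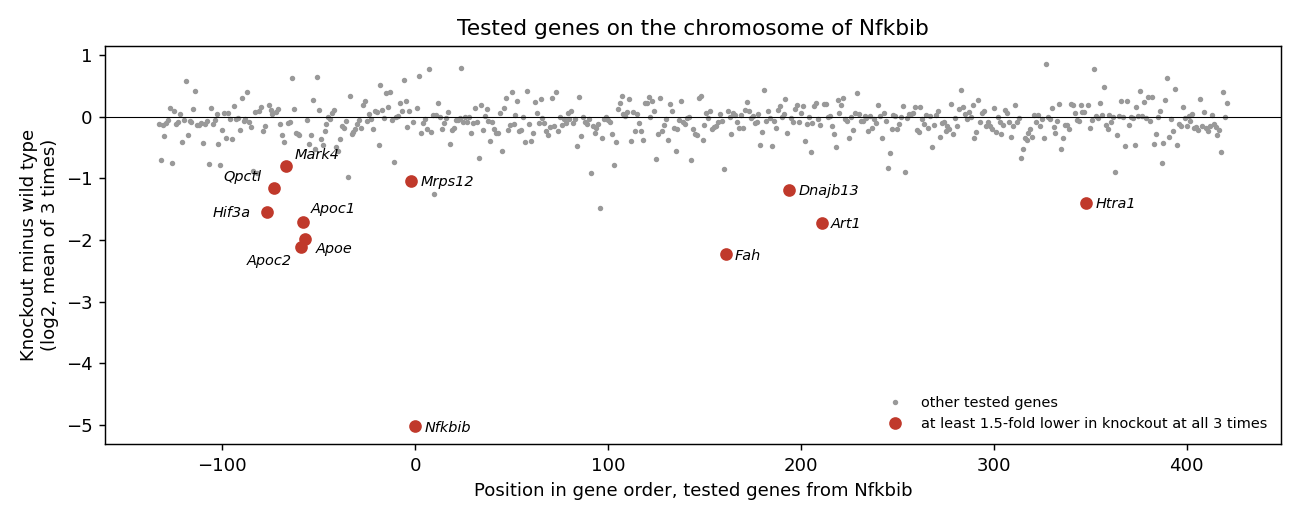
Knockout minus wild type, as the mean of the 3 times, for the tested genes of chromosome 7 in gene order, counted from Nfkbib. Genes at least 1.5-fold lower at all 3 times are named.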

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

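The differences in this part were listed because the LPS change went opposite ways in the 2 genotypes, by at least 1.5-fold each way, a minimum chosen after the data were seen; of the tests below, those of the scaling, of a weaker response and of the splits of the arrays were chosen before their results were seen and the others after. Each rests on 4 single arrays and was not tested. At 1 h the LPS change in knockout minus that in wild type was 3.84 for Dpf3, 1.87 for Abhd1, −1.48 for Cxcl9, −2.83 for Nkain1, −3.04 for Rasgrp4 and −2.59 for Slc16a11. At 5 h it was −3.61 for Hps1, 3.97 for Igha, −3.12 for Nkain1, −3.21 for Pard3b, −1.96 for Slc16a11, −4.73 for Slc30a3, 3.25 for Ypel1 and −3.89 for Zap70. Except for Cxcl9 at 5 h, where it read 8541 in wild type and 9498 in knockout, the signals of these genes were 243 or less on every array. A second probe set of Nkain1 read 60, 46.1 and 59.1 in wild type and 51.8, 50.7 and 54.9 in knockout at 0 h, 1 h and 5 h. All 14 differences kept opposite signs after quantile normalization and after median centring, and 12 and 10 of them kept 1.5-fold each way.

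Outside the tested genes, 3 of 1025 probe sets without a single gene name that passed the signal filter were at least 4-fold lower in knockout at all 3 times. They were listed because they belong to data that no comparison used. No gene is given for them in the annotation used here. They read 344 to 1645 on the wild-type arrays and 20.7 or less on the knockout arrays. The Y-chromosome genes Eif2s3y and Uty were likewise absent in knockout, so a difference of sex cannot be told apart from the knockout here.

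Genes lower in the knockout at all 3 times lay in excess on chromosome 7, with Nfkbib: 11 of 20 autosomal ones against 554 of 7283 tested genes (odds ratio 15.1). This count was made after the values were seen. Sex of the animals is argued against for the excess on 1 autosome, as Fisher's exact test gave p = 1.35e-05 with neighbours under 5 genes apart counted once; for the 9 genes on other autosomes sex cannot be told apart from the knockout, since each pair of arrays differs in both. DNA around Nfkbib that differs between the genotypes, such as sequence kept from the strain in which the deletion was made, may contribute: the 11 genes lay a median of 73 genes from Nfkbib against 146 for the others (one-sided permutation p = 0.043). With neighbours counted once, the same permutation test gave p = 0.31 for 8 genes at a median of 119, so the distance leaves this open. Sequence differences under the probes, which could lower a signal without a change in RNA, cannot be told apart with 3 other probe sets that passed the signal filter. Of these, 1, for Mark4, was at least 1.5-fold lower at all 3 times.

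Interferon-stimulated genes were higher in the knockout before LPS, though camera over the 3 times went from adjusted p = 5.2e-07 to adjusted p = 0.563 with an estimated correlation. Scaling between arrays is argued against by a list median of 0.32 after quantile normalization (0.3193 before rounding). LPS in the unstimulated knockout culture stays open: the median at 0 h of the 112 genes that LPS induces at both times lay at percentile 62.7 of random lists, but 9 of them were at least 1.5-fold higher and 12 lower, and 11 were under the floor in both genotypes. The 91 of them above the floor, without Nfkbib and the interferon-stimulated list, had a median of 0.02, and 9 reached 0.32. Of these 91 genes, 7 were at least 1.5-fold higher and 9 lower. The distance is less than the SD of the 91, which was 0.55. That SD is the spread of single genes and not the error of a median, so it cannot decide. Tnf (−0.51) and Tnfaip3 (−0.59) were lower, and Il1b (0.75) was higher. Differences between the animals other than genotype, sex included, cannot be told apart from the knockout: Xist stood 6.76 higher at 0 h, and each genotype has 1 array at this time. An effect of the absence of IκBβ on interferon signalling is a hypothesis that stays open.

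The median of cytokines was lower in the knockout at 1 h, with 14 of 22 members lower, but 5 were at least 1.5-fold higher against 4 lower, and camera over the 3 times gave adjusted p = 0.183 (adjusted p = 0.563 with an estimated correlation). A weaker LPS response of the whole knockout culture stays open. Other genes with the same mean LPS change at 1 h gave medians from −0.12 to 0.09, with −0.003 in the middle. The −0.20 of cytokines lay at percentile 0.11 of such draws. This was to exclude it, but a percentile of draws leaves out how far the members spread: their SD was 0.77, more than the distance of the medians. That SD is the spread of single genes and not the error of a median, so it cannot decide either. Other genes that LPS induces went both ways at 1 h: late LPS effectors (−0.16, percentile 0.06) and the sustained genes (−0.05, percentile 1.89, but 0.05 after median centring) were lower, immediate early genes (0.09, percentile 98.4) and negative feedback genes (0.10, percentile 98.7) were higher, and chemokines (−0.01, percentile 58.1) lay within the random range. Noise of single probe sets stays open, since only 1 other probe set exists for these 4 members; it belongs to Il12b and was lower (1 of 1). Sex and other differences between animals may also contribute and were not tested.

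The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene, and the highest of the others 0, so 1 of 10 splits gave as many. For gene lists the real split called 5, and the highest of the others 3, so 1 of 10 gave as many. Most of the other splits put both arrays of a time in the same group. As time is a term of the fit, fewer pairs of arrays then inform the split, and fewer calls are likely in advance. The other splits with 1 array of each time in both groups called 0 genes each, and 2, 0 and 1 lists. The splits thus decide nothing.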

How the results depend on the processing

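The alternatives with a minimum signal, without some chromosomes and with other random lists were chosen after the data were seen, and the others before. Of 241 comparisons of a count with its alternative, 151 stayed within 1.5 times and 90 did not. Of 1624 checks of a tested gene, 1510 kept direction and side of the threshold, 59 lost the call, 51 gained one and 4 changed direction. Unless stated, the cause was not tested.

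Quantile normalization moved 1 count: 1782 genes 2-fold lower at 5 h in knockout. Median centring shifts each array by its median, which fell at 5 h, so it turns falls into rises by construction. It gave 268 genes lower at 1 h, 2929 higher and 2027 lower at 5 h, and 2 higher and 4 lower for genotype. Within genotypes it gave 208 genes 2-fold lower in knockout at 1 h, 1778 higher and 1244 lower in wild type at 5 h, and 2044 and 1233 in knockout. It reversed the sustained class at 1 h (0.0527) and, at 5 h, Ccl6 (0.17), Aldoa (0.30) and Hprt (0.0883). The mean over probe sets reversed Ikbkg at 5 h (0.35) and knockout minus wild type of Socs3 at 0 h (−0.49).

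With the floor at the 10th percentile, 0 genes were lower by genotype, and 21 were higher and 25 lower at all 3 times. With the floor at the 40th percentile, 718 genes were lower at 1 h, and 1 higher and 3 lower by genotype. Genes 2-fold higher and lower in knockout were then 25 and 41 at 0 h, 42 and 91 at 1 h, and 61 and 109 at 5 h, with 7 lower at all 3 times; a higher floor shrinks low-signal folds by construction. The pseudocount gave 1 higher and 3 lower by genotype, and 51 and 83 at 1 h and 88 and 139 at 5 h.

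Without an expression filter, 146 genes were higher and 100 lower at 1 h and 0 lower by genotype. Knockout against wild type then gave 297 and 428 at 0 h, 247 and 544 at 1 h, 270 and 475 at 5 h, and 19 lower at all 3 times. At 1 h of LPS 726 genes were 2-fold higher and 653 lower in wild type, and 751 lower in knockout. With only genes above the median on all 6 arrays, fewer genes are counted by construction: knockout against wild type gave 2 and 7 at 0 h, 7 and 20 at 1 h and 22 and 42 at 5 h, with 2 higher and 5 lower at all 3 times. LPS then gave 224 and 97 genes in wild type and 229 and 121 in knockout at 1 h, 632 and 1630 in wild type and 1813 lower in knockout at 5 h, while limma called 706 lower at 1 h and 2 lower by genotype.

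Limma with a trend and robust prior gave 916 genes lower at 1 h, and 4 higher and 5 lower by genotype. Leave-one-out counts ranged from 100 to 362 higher and 12 to 346 lower at 1 h, 1115 to 1358 higher and 3057 to 3796 lower at 5 h, and 0 to 1 higher and 0 to 1 lower by genotype; fewer arrays enter, and the lone array of a time is assumed to vary like the others. With an estimated correlation camera called 5 lists at 1 h, 0 at 5 h and 0 by genotype, against 11, 11 and 5. With at least 200 on the brighter array, knockout against wild type gave 5 and 14 at 0 h, 19 and 34 at 1 h and 34 and 43 at 5 h. Without genes on the sex chromosomes and on the chromosome of Nfkbib, 4 genes were lower at all 3 times.

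Of 192 checks of a list or class median outside the random range, 143 stayed within 1 SD of random lists, 48 moved and 1 changed sign, and 65 of 69 percentiles kept their side of the range with the other matching. Of 2677 checks of knockout minus wild type of a named gene, 253 moved by more than the spread over genes and 1 reversed. Signals near the floor limit what can be read: 2-fold differences between the genotypes were mostly in genes under 200 on both arrays.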

Other observations

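The test in this part was chosen after the result was seen. Late-induced genes were higher in the knockout before LPS, with a median of 0.05 at 0 h. Without the interferon-stimulated list, 214 late genes had a median of 0.02 at 0 h (percentile 84.3 of random lists). The 110 sustained genes left without that list had a median of 0.00 (percentile 63.2).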
